A study of Mus musculus with 17 samples.

How the data were processed

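RNA captured after a 15 minute label, called new RNA here, was measured in 17 libraries from mouse embryonic stem cells of the E14tg2a line (129SV background). Both Erk genes had been knocked out in these cells and replaced by a cDNA for FLAG-ERK2 Q103A, a kinase with an enlarged ATP pocket that PP1 analogues can block. The cells also carried a cRAF-ErT2 cassette, a RAF kinase that 4-hydroxytamoxifen (4OHT) switches on. Per the labels' protocols, cells were kept for 24 h in serum with LIF and 250 nM PD173074, an inhibitor of FGF receptors, and were then left untreated or given 250 nM 4OHT for 2 h. The same was done with a MEK inhibitor at 1 µM or with PP1 at 2 µM. Ethynyl uridine at 5 mM was present for the last 15 minutes, and RNA that had taken it up was captured by click chemistry after DNase treatment of the total RNA. Libraries were made with the NEBNext Ultra 2 kit. The labels and the series description spell the MEK inhibitor's code in different ways, and the length of treatment with an inhibitor alone is not stated clearly, so this time is treated as unknown here.

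The deposited table holds counts of reads or fragments per gene symbol, whole numbers with 1 column per library and no normalization. Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with featureCounts. Their versions, the gene annotation, the feature type counted, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. The table has 25899 symbols, of which 25557 (98.7%) matched GENCODE mouse release 21, and 21720 were protein-coding genes there. Gene identifiers and mm10 coordinates come from this release, matched by symbol. Across genes within the table, the summed count had a Spearman's rho of 0.54 with the span of the gene (genes are not independent replicates). All 13 mitochondrial symbols had 0 counts in every library. All 17 columns were used.

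Because the strand setting is not known, reads from overlapping or antisense genes cannot be told apart. Among the genes named in the report this leaves the values of Slc7a7 (overlapping Oxa1l), Mfsd12 (Fzr1), Gng13 (Chtf18), Nab2 (Nemp1 and Stat6), Ppm1j, S100a3 (S100a2), Atp6v0a4 (Tmem213), Irak3 (Tmbim4), Bmp4 (Gm15217), Cyp51 (Akap9), Fdft1 (Ctsb), Fbxo15 (Timm21) and Junb (Prdx2) uncertain. Histone genes are a multigene family whose reads could be split between near-identical copies, so single histone genes are uncertain too.

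The libraries form 6 groups: DMSO (n = 2, clones b and c) and 4OHT, MEK inhibitor (MEKi), MEKi with 4OHT, PP1, and PP1 with 4OHT (n = 3 each, clones a, b and c). The replicates are 3 cell clones, so p-values measure how well a difference holds between clones of 1 cell line and say nothing of other lines or of repeated experiments. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by group (14907 genes kept), and a robust quasi-likelihood fit of all 17 libraries with 1 term per group. The fit had 11 residual degrees of freedom and a common biological coefficient of variation of 0.098. With 12 comparisons in all, 9 compared 2 groups and 3 were interactions, each the 4OHT effect under 1 condition minus the 4OHT effect under another. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (counts relative to the library total) after TMM scaling, given as mean ± SD over libraries. Log2 fold changes are given ± an approximate standard error, their absolute value over the square root of the quasi-likelihood F. It was not fitted directly and can be too small where a group has few counts.

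Genes were named by a rule. Mapk3 came first, as a gene the constructs concern. Then came the 10 largest rises and the 10 largest falls in each comparison of 4OHT with its own control, and 5 and 5 in each other comparison. These were taken among called genes with an average log2 CPM of at least 1 that moved the same way in every clone both groups have, passing over predicted and uninformative symbols. For the interactions the 5 and 5 genes of smallest adjusted p were taken. Up to 4 called members per gene list were allowed as examples, and a fixed set of 20 signalling and lineage genes could be given whether called or not. Results of some genes that this rule picks are not reported here.

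The 26 gene lists, written from general knowledge, were ERK feedback and ETS targets, immediate early genes, naive pluripotency, core pluripotency, formative and primed epiblast, primitive endoderm, primitive streak and mesoderm, trophoblast, neuroectoderm, fibroblast, 2-cell-like, cytoskeletal SRF targets, Wnt targets, BMP and Nodal targets, ribosome biogenesis, cell cycle, p53 targets, integrated stress and unfolded protein response, heat shock, cholesterol synthesis, oestrogen response, Src, YAP and adhesion targets, replication-dependent histones, long-lived abundant mRNAs, construct and pathway genes, and mitochondrial genes. The last could not be tested, since its genes had no counts, and 25 were tested. Each was compared with the other genes by camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01), adjusted over the lists of 1 comparison. The comparisons, the rule for naming genes, the lists and most alternatives were chosen before the data were examined. Overlaps between called genes were tested with Fisher's exact test, one-sided, over the 14907 genes. This test takes genes as independent and equally likely to be called, which they are not. Its p-values and chance counts do not measure the spread between clones.

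The alternatives planned were DESeq2's size factors in the same edgeR fit, library totals as the only scaling, no filter on low counts, a filter of at least 10 counts in every library of 1 group, DESeq2 1.42.0, limma-voom, clone as a replicate block, only the libraries of the groups compared, each library left out in turn, an estimated inter-gene correlation, fry, and genes that changed at least 2-fold. Those for normalized values were not applicable to counts. Alternatives added after the data were seen left out 14 high-count loci with or without TMM scaling, the 2 libraries of highest background or the 3 libraries with the largest share of counts in those loci, or kept only genes with an average log2 CPM of at least 3. The clone letters in the labels pair libraries across groups. After subtraction of group means, pairs of libraries from the same clone had a mean correlation across genes of 0.16 (from -0.38 to 0.53, 30 of 40 pairs above 0.1) and pairs from different clones of -0.079 (80 pairs, 20 above 0.1). The blocked value is printed where it changes a call or moves a count by more than 1.5 times.

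The fit was tested on simulated counts with the real genes' means and library sizes, in which 200 genes were changed by known amounts. For 4OHT against DMSO, 47.8% of genes changed 1.5-fold, 68.2% of those changed 2-fold and 79.7% of those changed 4-fold were recovered among 14656 genes, with 5.92% of calls false. For MEKi with 4OHT against MEKi these were 50%, 74.6% and 95.3%, with 2.5% false, among 14669 genes. For PP1 with 4OHT against PP1 they were 56.7%, 68.2% and 100%, with 5.06% false, among 14656 genes. For MEKi against DMSO they were 46.3%, 74.6% and 89.2%, with 7.32% false, among 14622 genes, and for PP1 against MEKi 47.7%, 80.6% and 86.4%, with 4.91% false, among 14698 genes. For the interaction of PP1 and MEKi they were 40.3%, 53.7% and 90.9%, with 7.48% false, among 14671 genes. In the same simulations, a list of 30 genes shifted by 0.5 log2 units was found by camera in each of these 6 comparisons and an unshifted list in none. Simulated genes were drawn independently, so this does not show how often camera calls an unshifted list of correlated genes. Besides the shifted list, 200 genes were changed, whereas 7752 of 14907 genes were called in the real comparison of 4OHT with DMSO. The rates of recovery and of false calls thus do not cover errors of scaling where so many genes change.

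Library totals ran from 5239690 to 11093390 counts. A count of 3 in the deepest library corresponds to 0.247 CPM. The background of each library was taken as the 5th percentile of CPM per Mb over 1466 genes with a span of at least 150000 bp. The 14 high-count loci are the symbols with a mean count of at least 1000 whose share of counts followed that of Cdk8 across libraries with a Pearson's r of at least 0.95.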

Results

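RNA captured after a 15 minute label was counted in 17 libraries of mouse embryonic stem cells. It is called new RNA below, although how much unlabelled RNA was captured with it was not measured. By design, 4OHT switches on ERK through cRAF-ErT2. A MEK inhibitor (MEKi) was meant to block MEK, and PP1 to block ERK2 Q103A itself. How far either blocked its target is not measured by these data. DMSO had 2 libraries (clones b and c), and 4OHT, MEKi, MEKi with 4OHT, PP1, and PP1 with 4OHT had 3 each (clones a, b and c). DMSO is labelled 0 h, as are MEKi and PP1 without 4OHT, and the labels do not say whether the DMSO cells were also kept for 2 h with vehicle. Totals were 11093390 and 10044412 counts in DMSO b and c, and 10349066, 7680990 and 9280691 in 4OHT a, b and c. MEKi a, b and c had 7408269, 7102570 and 9628690, and the MEKi with 4OHT libraries had 9218144, 8853293 and 9275860. PP1 a, b and c had 5239690, 9361752 and 8126013, and the PP1 with 4OHT libraries had 9808333, 9784904 and 7714017.

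Log2 CPM of libraries in the same group correlated across genes with Pearson's r from 0.976 to 0.991. The first principal component held 50% of the variance and placed the 3 4OHT libraries at 73.1 to 84, the 3 PP1 with 4OHT libraries at 16.6 to 18.6, and the other 11 libraries between -36.3 and -19. A set of 14 loci, among them Cdk8, Lars2, Zc3h7a and Jarid2, took 9.38% (4OHT a) to 42% (PP1 a) of a library's counts. With library totals as the only scaling, the median log2 fold change of all genes shifted to -0.32 for 4OHT against DMSO, 0.17 with MEKi and 0.12 with PP1, and with the 14 loci left out as well it was -0.27, 0.04 and -0.09.

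Mapk3, one of the genes that the constructs concern, encodes ERK1 and lies on chromosome 7 at 126759601 to 126765819 in mm10 (ENSMUSG00000063065.13). It had between 7.6 and 17.9 CPM in all 17 libraries. Counts per symbol do not separate intact from disrupted transcripts of a locus, so these levels do not check the knockout.

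After 2 h of 4OHT, which switches on ERK through cRAF-ErT2, the new RNA of 7752 genes differed from DMSO. Spry4, a feedback inhibitor of receptor signalling (chromosome 18, 38586247 to 38601415, ENSMUSG00000024427.7), rose from 114 ± 9.27 CPM (SD, n = 2) in DMSO to 2320 ± 146 (n = 3) in 4OHT, 20.4-fold (log2 4.35 ± 0.11, edgeR quasi-likelihood adjusted p = 8.3e-19). Egr1, an immediate early gene (chromosome 18, 34859823 to 34864984), rose 37.7-fold from 49.2 ± 11.2 to 1850 ± 47.5 CPM. Dusp6, which encodes an ERK phosphatase (chromosome 10, 99263231 to 99267489), rose 3.61-fold from 77 ± 9.09 to 278 ± 14.3 CPM. In the same comparison Prdm14, a regulator of naive pluripotency (chromosome 1, 13113457 to 13127163), fell 9.72-fold from 52.1 ± 1.58 to 5.56 ± 1.52 CPM, and Nanog (chromosome 6, 122707489 to 122714633) fell 2.21-fold from 329 ± 47.5 to 150 ± 30.4 CPM.

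In all, 3832 genes rose and 3920 fell in 4OHT against DMSO, of 14907 tested (edgeR quasi-likelihood, Benjamini-Hochberg). At least 2-fold changes numbered 952 up and 1796 down. With library totals as the only scaling 6116 were called and 21.1% of these rose, against 49.4% with TMM, and 28.5% of 7971 rose with library totals after the 14 loci had been left out. The largest rises were Ankrd63, at 14.7 ± 2.7 CPM against 0.0411 ± 0.0582 (1 count in the DMSO libraries together, so no fold is given), and Egr3 (log2 7.98 ± 0.34), Fosb (6.37 ± 0.33), Fosl2 (6.32 ± 0.24), Sox8 (6.30 ± 0.47), Cavin1 (6.02 ± 0.29), Lor (5.90 ± 0.55), S100a3 (5.75 ± 0.63), Phlda1 (5.71 ± 0.15) and Cyth4 (5.70 ± 0.42). Egr3 and Fosb encode immediate early transcription factors and stood at 0.365 ± 0.4 and 0.401 ± 0.218 CPM in DMSO. The largest falls were Tex26 (log2 -4.62 ± 0.42), Serpina3i (-4.16 ± 0.36), the Nodal antagonist Lefty1 (-3.90 ± 0.44), Nlrp9c (-3.85 ± 0.27), Ropn1 (-3.84 ± 0.46), Dhrs7 (-3.82 ± 0.45), Fxyd2 (-3.80 ± 0.44), Foxr2 (-3.62 ± 0.62), Gpr139 (-3.62 ± 0.26) and AI593442 (-3.60 ± 0.52). Tex26 and Foxr2 stood at 0.177 ± 0.157 and 0.211 ± 0.271 CPM in 4OHT, and Lor and Sox8 at 0.17 ± 0.109 and 0.18 ± 0.138 in DMSO. These means are under the 0.247 CPM of 3 counts in the deepest library, so the folds and ranks of these genes are uncertain. Each of the genes of largest rise or fall moved the same way in 2 of 2 clones that both groups have, as the rule for naming genes required.

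Among the signalling genes, Fos rose by 4.09 ± 0.20 on the log2 scale, Etv4 by 1.70 ± 0.12 and Myc by 1.47 ± 0.17. Etv5 rose by 0.65 ± 0.08, and this call was lost with library totals as the only scaling (edgeR adjusted p = 0.12). Among naive pluripotency factors, Tbx3 had a log2 fold change of -1.20 ± 0.12, Klf4 of -1.01 ± 0.08 and Esrrb of -0.44 ± 0.08, all called. Otx2, an early factor of primed pluripotency, fell by 0.67 ± 0.18 on the log2 scale. Values that were not called were Pou5f1 at 0.63 ± 0.28 (edgeR adjusted p = 0.08), Sox2 at 0.01 ± 0.11 (0.94), Fgf5 at -0.60 ± 0.41 (0.23), and the endoderm genes Gata6, Gata4 and Pdgfra at 0.04 ± 0.37, 0.34 ± 0.35 and -0.19 ± 0.34. Mapk3 was not called either (-0.03 ± 0.27, adjusted p = 0.95).

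**Figure D1:**
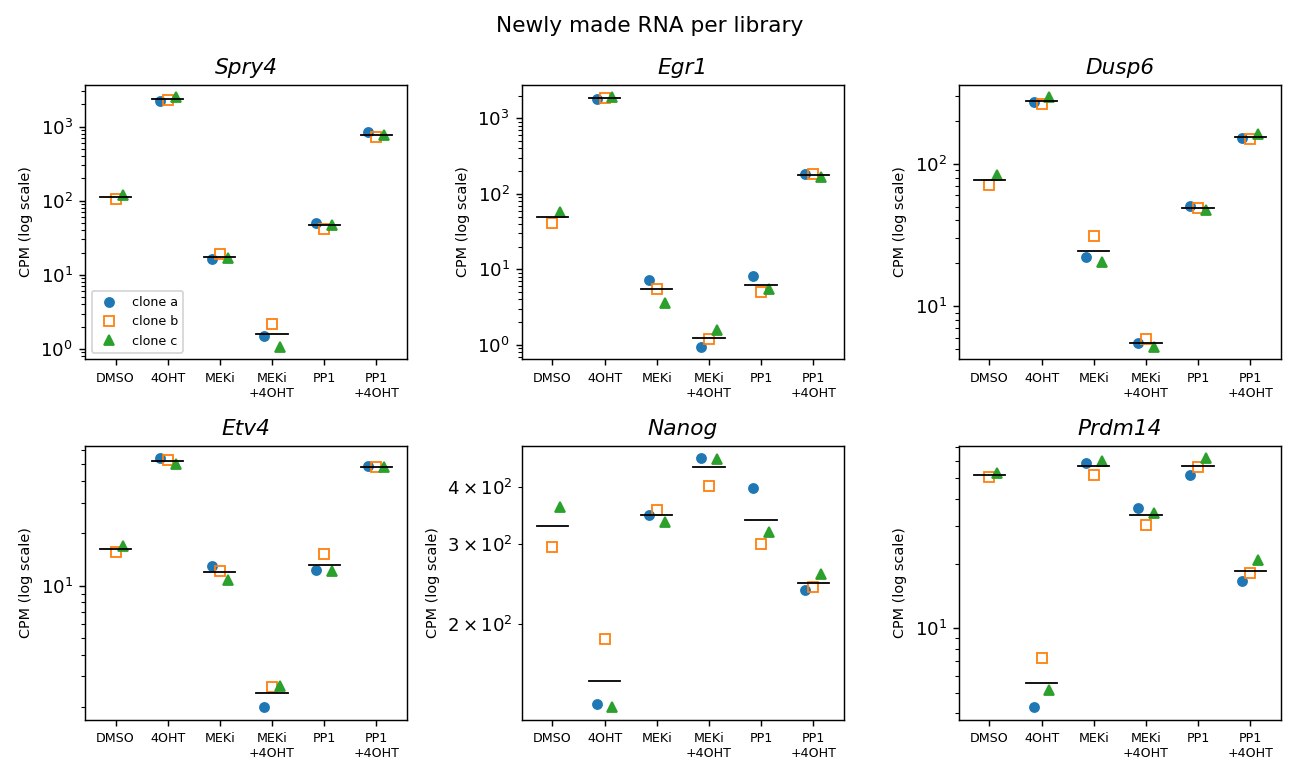
New RNA of Spry4, Egr1, Dusp6, Etv4, Nanog and Prdm14 in each library, in CPM on a log scale, by group; markers show the clones and black lines the group means. Spry4 averaged 114 CPM in DMSO, 2320 in 4OHT, 1.6 in MEKi with 4OHT and 775 in PP1 with 4OHT.

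ERK feedback and ETS targets had 23 members higher and 4 lower of 30 tested in 4OHT against DMSO (also 23 and 4 adjusted over the list alone), with a median log2 fold change of 1.49 (camera adjusted p = 2.1e-08, and adjusted p = 0.027 with an estimated correlation). Arc (5.70 ± 0.13) was among them. Immediate early genes had 23 higher and 2 lower of 29 (23 and 2 adjusted over the list alone), with a median of 1.53 (camera adjusted p = 5.4e-10, and adjusted p = 0.035 with an estimated correlation), including Junb (3.10 ± 0.15) and Nr4a1 (2.56 ± 0.12). Ribosome biogenesis genes had 24 of 30 higher and 0 lower (25 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 8.9e-07, and adjusted p = 0.45 with an estimated correlation). Cholesterol synthesis genes had 15 of 19 higher and 0 lower (15 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 8.1e-06, and adjusted p = 0.45 with an estimated correlation), among them Cyp51 (1.38 ± 0.12) and Msmo1 (1.20 ± 0.12). Cell cycle genes had 13 higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.69 with an estimated correlation). Heat shock genes had 7 and 0 (camera adjusted p = 0.0025, and adjusted p = 0.45 with an estimated correlation), and long-lived abundant mRNAs 8 and 0 (camera adjusted p = 0.0052, and adjusted p = 0.72 with an estimated correlation). Construct and pathway genes had 11 and 2 (camera adjusted p = 0.0091, and adjusted p = 0.17 with an estimated correlation). Cytoskeletal SRF targets had 10 and 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.032, and adjusted p = 0.72 with an estimated correlation). Where no count adjusted over the list alone is given, here and for the comparisons that follow, it was the same as the count over all genes.

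Naive pluripotency genes went both ways in 4OHT against DMSO, with 6 higher, among them Klf5 (1.12 ± 0.08), and 11 lower, among them Fbxo15 (-1.82 ± 0.09), and no shift of the list (camera adjusted p = 0.27). Formative and primed epiblast genes had 9 higher, with Pou3f1 at 3.82 ± 0.30 and Dnmt3a at 2.12 ± 0.12, and 4 lower (adjusted p = 0.14). Core pluripotency (3 higher, 1 lower; camera adjusted p = 0.55), primitive endoderm (2 and 8; 0.27), primitive streak and mesoderm (2 and 0; 0.56), trophoblast (5 and 1; 0.12), neuroectoderm (3 and 2; 0.58), fibroblast (1 and 2; 0.74) and 2-cell-like genes (0 and 0 of 2 tested; 0.58) were not called as lists. Neither were Wnt targets (4 higher, 5 lower; camera adjusted p = 0.86), integrated stress and unfolded protein response (5 and 2; 0.45), oestrogen response (2 and 4; 0.91), histones (7 and 1; 0.14), Src, YAP and adhesion targets (4 and 7; 0.58), BMP and Nodal targets (8 and 7, or 8 and 8 adjusted over the list alone; 0.91) and p53 targets (8 and 6; 0.58). In the last 3 and in the fibroblast list, the median and mean log2 fold changes had opposite signs (-0.14 and 0.05, 0.18 and -0.21, -0.08 and 0.18, and -0.20 and 0.15).

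With the MEK inhibitor, 4OHT no longer raised the ERK targets, and several of them fell instead. Spry4 fell 10.9-fold from 17.6 ± 1.53 CPM (n = 3) in MEKi to 1.6 ± 0.563 (n = 3) in MEKi with 4OHT (log2 -3.44 ± 0.17, edgeR quasi-likelihood adjusted p = 2.5e-12). Dusp6 fell 4.34-fold from 24.5 ± 5.78 to 5.53 ± 0.347 CPM, Myc fell 6.08-fold (log2 -2.60 ± 0.27) and Etv4 fell 4.92-fold (-2.30 ± 0.16). Egr1 fell 4.26-fold from 5.45 ± 1.8 to 1.24 ± 0.311 CPM. Ngfr, which encodes a neurotrophin receptor, rose 2.57-fold from 13.2 ± 1.28 to 33.9 ± 1.24 CPM.

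In this comparison 1140 genes rose and 1048 fell (edgeR quasi-likelihood). At least 2-fold changes numbered 32 up and 172 down. With library totals as the only scaling 1130 were called and 82.9% of these rose, against 52.1% with TMM, and 63.8% of 2462 rose with library totals after the 14 loci had been left out. Calls numbered 1051 without the 2 libraries of highest background, MEKi a and MEKi with 4OHT b (10.6 and 7.47 CPM per Mb, against 1.67 to 5.69 in the other 15), 1380 without MEKi a and 1437 without MEKi with 4OHT c. Besides Ngfr, the largest rises were Tgfb1i1 (log2 1.52 ± 0.31), Lhx5 (1.38 ± 0.43), Cacng5 (1.32 ± 0.34), S100a13 (1.22 ± 0.32), Padi2 (1.21 ± 0.20), Gng13 (1.19 ± 0.23), Pax5 (1.16 ± 0.28), Lfng (1.15 ± 0.37) and Mfsd12 (1.15 ± 0.15). Of these, Lhx5 was not called without MEKi a, b or c or MEKi with 4OHT a (edgeR adjusted p = 0.087, 0.083, 0.084 and 0.18). S100a13 was not called without MEKi a or b or MEKi with 4OHT c (edgeR adjusted p = 0.082, 0.072 and 0.086), nor Pax5 without MEKi c (0.056). Lfng was not called without MEKi b or c (edgeR adjusted p = 0.074 and 0.21) or without MEKi with 4OHT a, b or c (0.054, 0.086 and 0.13). The largest fall by fold, Med24 (log2 -4.31 ± 1.06, edgeR adjusted p = 0.019), rested on MEKi a, with 25241 counts against 495 and 2888 in MEKi b and c. Without MEKi a its log2 fold change was -1.62 (edgeR adjusted p = 0.063), and without MEKi with 4OHT a, b or c it was not called either (0.07, 0.06 and 0.069). The other large falls were Slc7a7 (log2 -2.68 ± 0.14), Spink1 (-2.65 ± 0.27), Id3 (-2.62 ± 0.39), Myo1f (-2.39 ± 0.27), Rerg (-2.38 ± 0.19) and Sh2d4b (-2.35 ± 0.17). Each was lower in 3 of 3 clones, as the rule for naming genes required.

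Etv5 (log2 -0.91 ± 0.07), Prdm14 (-0.76 ± 0.11) and Otx2 (-0.82 ± 0.17) fell with 4OHT in the presence of MEKi. Klf4 at -0.22 ± 0.07 (edgeR adjusted p = 0.042) lost its call without MEKi a or b or MEKi with 4OHT a, b or c (0.075, 0.11, 0.088, 0.098 and 0.075) and with library totals (0.86). Fgf5 at -1.40 ± 0.40 (edgeR adjusted p = 0.021) lost its call without MEKi a or MEKi with 4OHT a or b (0.11, 0.065 and 0.066) and with library totals (0.076). Esrrb at -0.19 ± 0.07 (edgeR adjusted p = 0.067) and Tbx3 at -0.25 ± 0.11 (0.14) were called only with clone as a block (0.043 and 0.011). Values not called were Nanog at 0.35 ± 0.12 (edgeR adjusted p = 0.058), Fos at -0.10 ± 0.36 (0.9), Pou5f1 at -0.13 ± 0.25 (0.79) and Mapk3 at 0.18 ± 0.25 (0.7).

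In MEKi with 4OHT against MEKi, ERK feedback and ETS targets had 0 members higher and 13 lower (1 and 16 adjusted over the list alone), with a median log2 fold change of -0.32 (camera adjusted p = 1.5e-12, and adjusted p = 0.0048 with an estimated correlation). Examples were Etv1 (-2.12 ± 0.12) and Spred1 (-1.52 ± 0.08). Naive pluripotency genes had 1 higher and 11 lower (2 and 12 adjusted over the list alone), with Dppa2 at -1.20 ± 0.10 and Klf5 at -0.84 ± 0.07 (camera adjusted p = 2e-06, and adjusted p = 0.052 with an estimated correlation). Formative and primed epiblast genes had 1 higher and 10 lower (1 and 12 adjusted over the list alone; camera adjusted p = 8.1e-07, and adjusted p = 0.052 with an estimated correlation). Core pluripotency genes had 0 higher and 6 lower (0 and 7 adjusted over the list alone; camera adjusted p = 6.4e-06, and adjusted p = 0.27 with an estimated correlation), and Wnt targets 0 and 3 (camera adjusted p = 0.0021, and adjusted p = 0.052 with an estimated correlation). Going up were cholesterol synthesis genes, 15 of 19 (17 adjusted over the list alone) with a median of 0.58 (camera adjusted p = 5.8e-11, and adjusted p = 0.16 with an estimated correlation), among them Msmo1 (0.90 ± 0.11) and Fdft1 (0.73 ± 0.09). p53 targets had 12 of 20 higher (13 adjusted over the list alone; camera adjusted p = 7.2e-07, and adjusted p = 0.052 with an estimated correlation), with Cdkn1a at 0.95. Histones, with 0 higher and 2 lower and a median of -0.27 (camera adjusted p = 0.03), had an adjusted p = 0.87 with an estimated correlation, and a median of -0.02 (camera adjusted p = 0.69) without the 3 libraries of largest loci share (4OHT b, MEKi b and PP1 a). Immediate early genes (3 higher, 2 lower; camera adjusted p = 0.53) and ribosome biogenesis genes (0 and 1; 0.71) were not called as lists. The immediate early median was 0.11 and the mean -0.02.

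With PP1, 4OHT still raised Egr1, Spry4, Dusp6 and Etv4. Egr1 rose 30-fold from 6.25 ± 1.67 CPM (n = 3) in PP1 to 176 ± 8.37 (n = 3) in PP1 with 4OHT (log2 4.91 ± 0.17, edgeR quasi-likelihood adjusted p = 1.7e-12), and Spry4 rose 16.8-fold from 46.5 ± 4.24 to 775 ± 55.7 CPM. Dusp6 rose 3.17-fold from 49 ± 1.31 to 155 ± 6.62 CPM and Etv4 rose 3.61-fold from 13.2 ± 1.76 to 48.4 ± 0.566 CPM. Prdm14 fell 3.11-fold from 56.9 ± 5.22 to 18.5 ± 2.13 CPM.

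In all, 2748 genes rose and 1913 fell (edgeR quasi-likelihood). At least 2-fold changes numbered 155 up and 523 down. With library totals as the only scaling 2668 were called and 76.6% of these rose, against 59% with TMM, and 42.5% of 4475 rose with library totals after the 14 loci had been left out. The largest rises after Egr1 and Spry4 were Fosb (log2 2.84 ± 0.60), Plaur (2.43 ± 0.15), Hs3st3b1 (2.42 ± 0.17), Ppm1j (2.39 ± 0.18), Twist1 (2.32 ± 0.57), Pla2g7 (2.23 ± 0.13), Nab2 (2.19 ± 0.12) and Phlda1 (2.12 ± 0.16). Fosb stood at 0.167 ± 0.145 CPM in PP1, under the 0.247 CPM of 3 counts in the deepest library, so its fold and rank are uncertain. Nab2 encodes a corepressor of EGR factors. The largest falls were Hrh2 (log2 -2.44 ± 0.35), Spic (-2.30 ± 0.30), Pdzph1 (-2.25 ± 0.46), Slc2a2 (-2.25 ± 0.43), Atp6v0a4 (-2.10 ± 0.22), Spns3 (-2.05 ± 0.46), Rit2 (-2.04 ± 0.33), Gfra2 (-2.02 ± 0.44), Vwf (-2 ± 0.19) and Foxi3 (-2 ± 0.41). All of these moved the same way in 3 of 3 clones, as the rule for naming genes required.

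Fos (log2 2.00 ± 0.23), Myc (1.56 ± 0.16) and Etv5 (0.41 ± 0.07) also rose with 4OHT in PP1. Nanog had a log2 fold change of -0.46 ± 0.12 (edgeR adjusted p = 0.0078) and Klf4 of -0.45 ± 0.07 (7.7e-05), both uncalled with library totals (0.1 and 0.11). Esrrb at 0.23 ± 0.07 (edgeR adjusted p = 0.015) was higher in 3 of 3 clones, and was at 0.13 and not called without PP1 with 4OHT a (0.17). Tbx3 at -0.38 ± 0.11 (edgeR adjusted p = 0.014) and Gata6 at -1.19 ± 0.37 (0.016) were lower in 3 of 3 clones. Tbx3 was at -0.33 without PP1 c (edgeR adjusted p = 0.062) and Gata6 at -0.98 without PP1 with 4OHT b (0.079), not called. The calls of Esrrb, Tbx3 and Gata6 were lost with library totals as well (edgeR adjusted p = 0.12, 0.35 and 0.06). Values not called were Mapk3 at 0.22 ± 0.26 (edgeR adjusted p = 0.55), Pou5f1 at 0.32 ± 0.25 (0.36), Sox2 at 0.03 ± 0.10 (0.82) and Otx2 at -0.11 ± 0.16 (0.62).

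With PP1, ERK feedback and ETS targets had 20 members higher and 2 lower with 4OHT (20 and 3 adjusted over the list alone), with a median log2 fold change of 0.74 (camera adjusted p = 4.8e-10, and adjusted p = 0.013 with an estimated correlation), among them Hbegf (1.97 ± 0.11). Immediate early genes had 20 higher and 1 lower (21 and 1 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 9.2e-07, and adjusted p = 0.15 with an estimated correlation). Ribosome biogenesis genes had 21 higher and 0 lower (23 adjusted over the list alone; camera adjusted p = 2.4e-08, and adjusted p = 0.37 with an estimated correlation). Cholesterol synthesis genes had 18 of 19 higher (19 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 6.8e-11, and adjusted p = 0.2 with an estimated correlation), among them Nsdhl (1.18 ± 0.11) and Fdft1 (1.14 ± 0.09). p53 targets had 13 higher and 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 0.00028, and adjusted p = 0.2 with an estimated correlation). Histones had 0 higher and 7 lower (0 and 8 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 0.00028, and adjusted p = 0.8 with an estimated correlation). The 14 loci took 16.1 to 42% of counts in PP1 and 10.9 to 19.1% in PP1 with 4OHT, and without the 3 libraries of largest loci share the histone median was -0.34 (camera adjusted p = 0.011). Primitive endoderm genes had 2 higher and 10 lower, with a median of -0.50 (camera adjusted p = 0.0055, and adjusted p = 0.2 with an estimated correlation), and were not called among genes with an average log2 CPM of at least 3 (adjusted p = 0.41). Cytoskeletal SRF targets (median 0.09, mean -0.03) and BMP and Nodal targets (0.15 and -0.03) were not called, and their medians and means differed in sign.

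The 3 comparisons of 4OHT with its own control share no libraries, so their called genes can be compared. Chance here takes genes as independent and equally likely to be called, so the p-values of the overlaps overstate the evidence. Of the genes that rose without inhibitor, 1893 also rose with PP1, where chance gives 706.4 (ratio 2.68), and 511 rose with MEKi, where chance gives 293 (ratio 1.74, Fisher's exact test, p = 3.26e-48). Of those that fell without inhibitor, 1403 fell with PP1 (503 by chance, ratio 2.79) and 458 fell with MEKi (275.6 by chance, ratio 1.66, Fisher's exact test, p = 8.52e-37). Between MEKi and PP1, 608 genes rose in both (ratio 2.89) and 321 fell in both (2.39), while 235 fell with MEKi and rose with PP1 (193.2 by chance, ratio 1.22, Fisher's exact test, p = 0.000418). Genes that rose without inhibitor and fell with MEKi numbered 280, against 269.4 by chance (Fisher's exact test, p = 0.229). The remaining opposite calls were fewer than by chance. They were 246 that fell without inhibitor and rose with MEKi (299.8 by chance) and 81 that rose with MEKi and fell with PP1 (146.3). With PP1, 50 fell that rose without inhibitor (491.8) and 90 rose that fell without it (722.6). With library totals as the only scaling the shared counts were 646 and 175 for rises with PP1 and MEKi, 500 and 64 for falls, 9 for falls with both inhibitors, 88 for falls with MEKi and rises with PP1, and 60 for rises without inhibitor and falls with MEKi. Under that scaling 1293 genes rose and 4823 fell without inhibitor, 937 and 193 with MEKi, and 2043 and 625 with PP1. Chance counts were not computed for it, so the ratios above hold for TMM only. The 3832 genes that rose without inhibitor had a median log2 fold change of 0.61 there, 0.28 with PP1 (0.28 to 0.29 over 3 clones) and 0.05 with MEKi (0.00 to 0.10). The 3920 that fell had a median of -0.93, and of -0.28 with PP1 (-0.32 to -0.16) and -0.04 with MEKi (-0.07 to -0.01), the last 2 medians becoming -0.117 and 0.139 with library totals. For the genes that rose, library totals gave 0.514 with PP1 and 0.224 with MEKi. Both sets of genes were chosen by their calls in 4OHT against DMSO. Their medians of 0.61 and -0.93 there are thus enlarged by that choice, and those with an inhibitor are not. The drop with an inhibitor can be overstated for that reason.

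**Figure D2:**
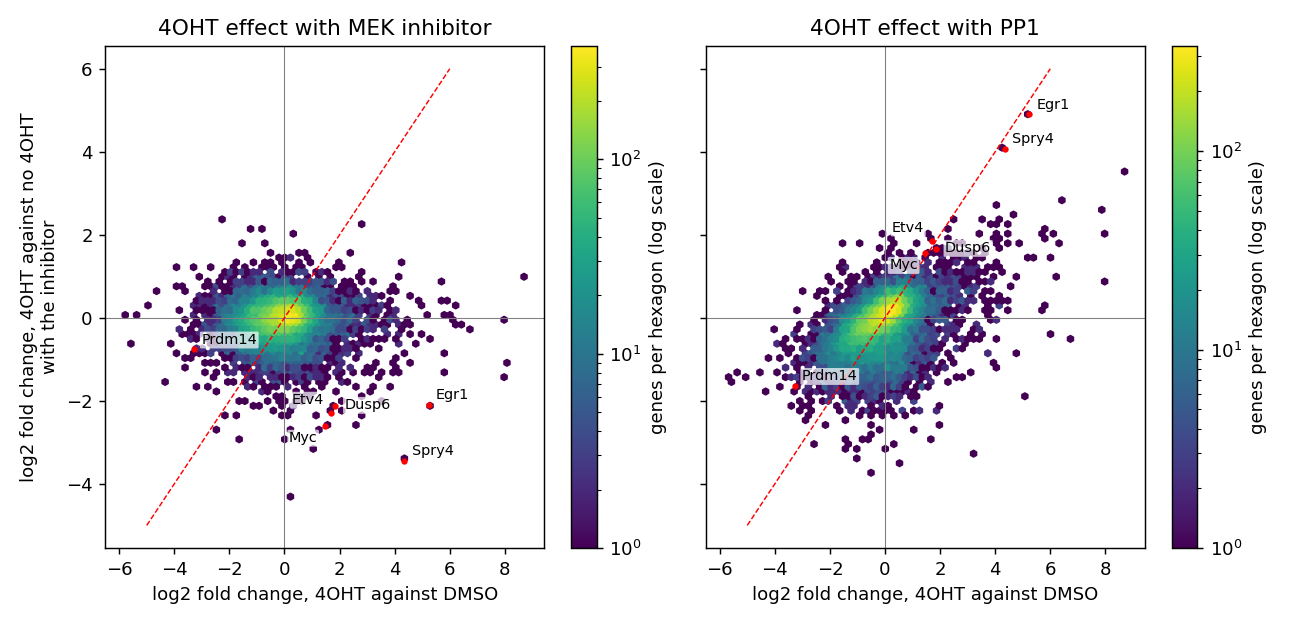
Log2 fold change of each tested gene in 4OHT against DMSO (horizontal) and with 4OHT in MEKi (left) or in PP1 (right), as density of genes; the dashed line marks equal changes and red points are Spry4, Egr1, Dusp6, Etv4, Myc and Prdm14. Spry4 lies at 4.35 without inhibitor, -3.44 with MEKi and 4.07 with PP1.

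Without 4OHT, the MEK inhibitor lowered several of the ERK targets below their level in DMSO. Egr1 fell 9.24-fold from 49.2 ± 11.2 CPM (n = 2) to 5.45 ± 1.8 (n = 3) (log2 -3.21 ± 0.18, edgeR quasi-likelihood adjusted p = 6.8e-09), and Spry4 fell 6.51-fold from 114 ± 9.27 to 17.6 ± 1.53 CPM. Id3, a target of BMP signalling, fell 5-fold from 12.5 ± 0.98 to 2.66 ± 1.44 CPM, and Dusp6 fell 3.2-fold to 24.5 ± 5.78 CPM. Myc had a log2 fold change of -1.53 ± 0.19, and Fos had one of -1.86 ± 0.30, which was not called without DMSO c (edgeR adjusted p = 0.14).

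In this comparison 12 genes rose and 67 fell (edgeR quasi-likelihood), against 14 and 106 with clone as a block. With library totals 1 rose and 19 fell, and leaving out DMSO b, DMSO c, MEKi a, MEKi b or MEKi c left 33, 19, 38, 52 and 44 calls. The largest rises were Hist1h2ad (log2 1.63 ± 0.38), Fat3 (1.49 ± 0.34), Hist1h3d (1.29 ± 0.18), Hist1h4j (1.22 ± 0.28) and Hist2h3c1 (1.13 ± 0.22). Each was higher in 2 of 2 clones, as the rule for naming genes required. None of these 5 was called without DMSO c (edgeR adjusted p = 0.62, 0.61, 0.056, 0.5 and 0.3), and without DMSO b only Hist1h3d of the 5 was. Without DMSO b the adjusted p was 0.28 for Hist1h2ad, 0.3 for Fat3, 0.36 for Hist1h4j and 0.16 for Hist2h3c1 (edgeR). Without MEKi a, the adjusted p was 0.083 for Hist1h2ad, 0.25 for Fat3, 0.15 for Hist1h4j and 0.11 for Hist2h3c1 (edgeR). Fat3 was at 0.1 and 0.052 without MEKi b and c, Hist1h2ad at 0.16 and 0.066, and Hist1h4j at 0.14 and 0.051. Histones had 4 members higher and 0 lower (18 adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 7.1e-20, and adjusted p = 0.25 with an estimated correlation). The 14 loci took 15.1 to 32.6% of counts in MEKi and 12.4 to 15.7% in DMSO, and without the 3 libraries of largest loci share the median was 0.70 (camera adjusted p = 4.2e-18). Of the ERK feedback and ETS targets, 0 were higher and 6 lower (0 and 16 adjusted over the list alone; camera adjusted p = 1.6e-09, and adjusted p = 0.016 with an estimated correlation), with Spry2 at -1.18 ± 0.09. Immediate early genes had 0 higher and 4 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.25 with an estimated correlation). Mapk3 (log2 -0.26 ± 0.28), Etv4 (-0.44 ± 0.13), Nanog (0.08 ± 0.13) and Prdm14 (0.13 ± 0.12) were not called (edgeR adjusted p = 0.77, 0.16, 0.88 and 0.74).

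PP1 alone changed fewer genes. Egr1 fell 8.36-fold from 49.2 ± 11.2 CPM (n = 2) in DMSO to 6.25 ± 1.67 (n = 3) in PP1 (log2 -3.06 ± 0.19, edgeR quasi-likelihood adjusted p = 2.8e-08), and Spry4 fell 2.47-fold from 114 ± 9.27 to 46.5 ± 4.24 CPM. In all, 12 genes rose and 24 fell, or 36 together. The 12 that rose made up 33.3% of the calls, against 57.1% of 14 with library totals and 49.4% of 85 with DESeq2. Leaving out DMSO b, DMSO c, PP1 a or PP1 b left 4, 3, 14 and 9 calls.

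Further falls with PP1 were Bet1 (log2 -0.84 ± 0.14), Asb1 (-0.72 ± 0.15) and Zfp933 (-0.66 ± 0.13), of which none was called without DMSO c (edgeR adjusted p = 0.4, 0.63 and 0.49). Asb1 was not called without DMSO b, PP1 b or PP1 c (edgeR adjusted p = 0.23, 0.16 and 0.088) and Zfp933 not without DMSO b or PP1 c (0.24 and 0.087). Dusp6 at -0.65 ± 0.11 (edgeR adjusted p = 0.012) was not called without DMSO b, DMSO c or PP1 b (0.058, 0.57 and 0.06). Rises were Hist1h2ae (log2 1.43 ± 0.29), Hist1h4j (1.41 ± 0.28), Hist1h3d (1.37 ± 0.18), Hist1h3a (1.23 ± 0.25) and Hist1h4i (1.21 ± 0.17). Without DMSO c none of these 5 was called (edgeR adjusted p = 0.57, 0.49, 0.093, 0.4 and 0.093), and without DMSO b only Hist1h3d was. Without DMSO b the edgeR adjusted p was 0.45 for Hist1h2ae, 0.37 for Hist1h4j, 0.47 for Hist1h3a and 0.056 for Hist1h4i. Hist1h2ae, Hist1h4j and Hist1h3a were not called without PP1 a (edgeR adjusted p = 0.076, 0.1 and 0.11) or PP1 b (0.07, 0.15 and 0.083), and Hist1h2ae and Hist1h3a not with clone as a block (0.07 and 0.058). As a list, histones had 5 higher and 0 lower (21 of 21 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 3.4e-28, and adjusted p = 0.22 with an estimated correlation), or 0.94 (camera adjusted p = 3.5e-33) without the 3 libraries of largest loci share. The share of counts in the 14 loci ran from 12.4 to 15.7% in the DMSO libraries, 15.1 to 32.6% in MEKi, 16.1 to 42% in PP1, 12.4 to 16.1% in MEKi with 4OHT and 10.9 to 19.1% in PP1 with 4OHT, with MEKi b and PP1 a the highest. Of the ERK feedback and ETS targets, 0 were higher and 2 lower (0 and 6 adjusted over the list alone; camera adjusted p = 0.003, and adjusted p = 0.25 with an estimated correlation). Myc (log2 -0.56 ± 0.18), Fos (-1.02 ± 0.27) and Mapk3 (-0.21 ± 0.28) were not called (edgeR adjusted p = 0.22, 0.13 and 0.82).

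Set directly against each other without 4OHT, the inhibitors differed at 11 genes, all of them higher in PP1 by edgeR. Id3 was 4.17-fold higher in PP1, at 10.4 ± 0.641 CPM (n = 3) against 2.66 ± 1.44 (n = 3) (log2 2.06 ± 0.23, edgeR quasi-likelihood adjusted p = 2.5e-05). Spry4 was 2.64-fold higher (1.40 ± 0.11), Dusp6 2.03-fold (1.02 ± 0.11), Spry2 1.75-fold (0.80 ± 0.09) and Noct 1.58-fold (0.66 ± 0.10). In all 11 genes were higher and 0 lower by edgeR, with 606 genes at an unadjusted p under 0.05. By limma-voom 12 were higher and 0 lower, and by DESeq2 19 were higher and 1 lower. Without MEKi c, PP1 b or PP1 c the edgeR count was 6, 6 and 7, and Noct was not called without PP1 b (edgeR adjusted p = 0.088). With library totals as the only scaling 3 were called, Spry2 and Noct not among them (edgeR adjusted p = 0.39 and 1). The list of ERK feedback and ETS targets had 3 higher and 0 lower (5 adjusted over the list alone; camera adjusted p = 3.6e-07, and adjusted p = 0.041 with an estimated correlation). Egr1 did not differ between the inhibitors by this test (log2 0.14 ± 0.24, edgeR adjusted p = 0.98), nor did Mapk3 (0.06 ± 0.27, 0.99).

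Within 4OHT, the MEK inhibitor lowered many genes that 4OHT had raised. Spry4 was 1440-fold lower in MEKi with 4OHT than in 4OHT, at 1.6 ± 0.563 against 2320 ± 146 CPM (n = 3 each; log2 -10.49 ± 0.14, edgeR quasi-likelihood adjusted p = 5.2e-25). Egr1 was 1480-fold lower, at 1.24 ± 0.311 against 1850 ± 47.5 CPM, and Phlda1 215-fold lower. Nanog was 2.98-fold higher, at 443 ± 34.5 against 150 ± 30.4 CPM. In all 4233 genes were higher and 4230 lower (edgeR quasi-likelihood), with 80% of 7337 calls higher under library totals (74.1% of 8898 with the 14 loci left out as well). Egr3 (0.0976 ± 0.00244 against 92 ± 10.2 CPM, 1 count per library with MEKi) and Ankrd63 (0.16 ± 0.197 against 14.7 ± 2.7) were among the largest falls. The largest rises were Tex26 (log2 5.04 ± 0.39), Lefty1 (4.27 ± 0.41), AI593442 (4.23 ± 0.47), Ropn1 (4.22 ± 0.43) and Rasgef1a (4.02 ± 0.25). Tex26 stood at 0.177 ± 0.157 CPM in 4OHT, under the 0.247 CPM of 3 counts in the deepest library, so its fold and rank are uncertain. Mapk3 was not called (log2 -0.06 ± 0.25, edgeR adjusted p = 0.85). The list of ERK feedback and ETS targets had 4 higher and 24 lower (camera adjusted p = 4.3e-12, and adjusted p = 0.0056 with an estimated correlation), and immediate early genes 2 and 22 (3 and 22 adjusted over the list alone; camera adjusted p = 5.1e-09, and adjusted p = 0.054 with an estimated correlation).

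Within 4OHT, PP1 lowered Spry4, Egr1 and Dusp6 by less than the MEK inhibitor did. Spry4 was 2.99-fold lower in PP1 with 4OHT than in 4OHT, at 775 ± 55.7 against 2320 ± 146 CPM (n = 3 each; log2 -1.58 ± 0.08, edgeR quasi-likelihood adjusted p = 3.9e-13). Egr1 was 10.5-fold lower (-3.39 ± 0.13), Fos 8.62-fold (-3.11 ± 0.16) and Dusp6 1.79-fold (-0.84 ± 0.09). Etv4 at -0.12 ± 0.10 was not called (edgeR adjusted p = 0.38). Prdm14 was 3.43-fold higher (1.78 ± 0.16) and Nanog 1.65-fold (0.72 ± 0.12). Higher genes numbered 3188 and lower ones 3050 (edgeR quasi-likelihood), with 79.8% of 4787 calls higher under library totals (73.2% of 6668 with the 14 loci left out as well). The largest falls were Egr3 (log2 -6.12 ± 0.24), Cyth4 (-5.27 ± 0.35), Fosb (-4.97 ± 0.25), Aldh1a3 (-4.75 ± 0.38) and Ankrd63 (-4.67 ± 0.41). The largest rises were Tex26 (3.38 ± 0.46), Foxr2 (3.36 ± 0.61), Lefty1 (3.13 ± 0.43), Serpina3i (3.02 ± 0.38) and Fxyd2 (2.94 ± 0.45). Tex26 and Foxr2 stood at 0.177 ± 0.157 and 0.211 ± 0.271 CPM in 4OHT, under the 0.247 CPM of 3 counts in the deepest library. Their folds and ranks are uncertain. Mapk3 was not called (0.04 ± 0.25, edgeR adjusted p = 0.93). Myc at -0.47 ± 0.14 (edgeR adjusted p = 0.0085) was not called without 4OHT b or PP1 with 4OHT a (0.05 and 0.054) or with library totals (0.26). Among ERK feedback and ETS targets were 6 higher and 18 lower (camera adjusted p = 7.1e-05, and adjusted p = 0.086 with an estimated correlation), and immediate early genes 1 and 20 (2 and 20 adjusted over the list alone; camera adjusted p = 2.7e-10, and adjusted p = 0.063 with an estimated correlation).

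With 4OHT present, PP1 and the MEK inhibitor left different levels of many ERK targets. Spry4 was 482-fold higher in PP1 with 4OHT than in MEKi with 4OHT, at 775 ± 55.7 against 1.6 ± 0.563 CPM (n = 3 each; log2 8.91 ± 0.14, edgeR quasi-likelihood adjusted p = 1.4e-23). Egr1 was 141-fold higher, Id3 38-fold, Myc 34.8-fold and Dusp6 28-fold. Nanog was 1.8-fold lower (log2 -0.85 ± 0.12) and Prdm14 1.83-fold lower (-0.87 ± 0.12), whereas Sox2 (0.54 ± 0.10) and Otx2 (0.86 ± 0.16) were higher. In all 2263 genes were higher and 1936 lower (edgeR quasi-likelihood), with 30.7% of 2153 calls higher under library totals (31.1% of 4525 with the 14 loci left out as well) against 53.9% with TMM. The largest falls were Foxi3 (log2 -2.91 ± 0.36), Spic (-2.66 ± 0.29), Atp6v0a4 (-2.53 ± 0.21), Cyp4f39 (-2.52 ± 0.37) and Cacng5 (-2.41 ± 0.37). Pou5f1 at 0.89 ± 0.25 (edgeR adjusted p = 0.019) was not called without MEKi with 4OHT a, b or c (0.067, 0.079 and 0.052) or PP1 with 4OHT b or c (0.061 and 0.054). Mapk3 (0.10 ± 0.25) was not called (edgeR adjusted p = 0.8).

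As lists, in the same comparison, ERK feedback and ETS targets had 22 members higher and 2 lower (camera adjusted p = 5.6e-20, and adjusted p = 0.00062 with an estimated correlation). Core pluripotency genes had 12 of 14 higher and 0 lower (camera adjusted p = 1.1e-07, and adjusted p = 0.18 with an estimated correlation). Formative and primed epiblast genes had 10 and 0 (camera adjusted p = 1.3e-05, and adjusted p = 0.11 with an estimated correlation), and ribosome biogenesis genes 25 and 0 (28 and 0 adjusted over the list alone; camera adjusted p = 5.1e-12, and adjusted p = 0.18 with an estimated correlation). Primitive endoderm genes had 2 higher and 11 lower (2 and 12 adjusted over the list alone; camera adjusted p = 0.0096, and adjusted p = 0.18 with an estimated correlation), with Gata6 at -1.68 ± 0.34.

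Whether the 4OHT effect itself differed between conditions was tested by interaction terms. The 4OHT effect with MEKi differed from that without inhibitor at 6022 genes, 3147 higher and 2875 lower (edgeR quasi-likelihood), with 86.5% of 5496 calls higher under library totals (76.5% of 6571 with the 14 loci left out as well). Spry4 (log2 -7.79 ± 0.19, edgeR adjusted p = 4.1e-19), Arc (-5.66 ± 0.18), Pla2g7 (-5.59 ± 0.22), Hbegf (-4.50 ± 0.17) and Spred1 (-3.03 ± 0.12) had the smallest adjusted p among lower genes. Arhgap8 (2.88 ± 0.17), St8sia1 (2.60 ± 0.16), Mcf2 (2.55 ± 0.14), Azin2 (2.30 ± 0.14) and Kit (1.90 ± 0.11) had them among higher genes. Nanog (1.5 ± 0.18) and Prdm14 (2.52 ± 0.20) were also higher. ERK feedback and ETS targets had 3 higher and 24 lower (4 and 24 adjusted over the list alone; camera adjusted p = 3.3e-14, and adjusted p = 0.0028 with an estimated correlation), and immediate early genes 3 and 21 (camera adjusted p = 1.9e-09, and adjusted p = 0.046 with an estimated correlation).

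The 4OHT effect with PP1 differed from that without inhibitor at 3943 genes, 2246 higher and 1697 lower (edgeR quasi-likelihood), with 89.3% of 4157 calls higher under library totals (75.6% of 4668 with the 14 loci left out as well). Not called here were Spry4 (log2 -0.28 ± 0.13, edgeR adjusted p = 0.12), Dusp6 (-0.19 ± 0.15, 0.37), Egr1 (-0.33 ± 0.24, 0.33), Etv4 (0.16 ± 0.17, 0.54), Etv5 (-0.24 ± 0.11, 0.095) and Myc (0.09 ± 0.23, 0.81), so that no difference in their fold response was detected. Fos (-2.09 ± 0.33), Arc (-3.67 ± 0.17), Twsg1 (-2.94 ± 0.13), Srxn1 (-2.93 ± 0.15), Gprc5a (-2.66 ± 0.15) and Anxa7 (-2.42 ± 0.13) responded less with PP1. Higher were St8sia1 (1.98 ± 0.16), Azin2 (1.87 ± 0.15), Irak3 (1.64 ± 0.14), Prdm14 (1.64 ± 0.20), Tet1 (1.35 ± 0.11), Lifr (1.12 ± 0.09), Klf4 (0.57 ± 0.11) and Esrrb (0.67 ± 0.11). Nanog at 0.68 ± 0.18 (edgeR adjusted p = 0.0094) was not called without DMSO c, 4OHT a, 4OHT c or PP1 with 4OHT b (0.17, 0.078, 0.073 and 0.053). Immediate early genes had 0 higher and 16 lower (1 and 18 adjusted over the list alone; camera adjusted p = 9e-09, and adjusted p = 0.086 with an estimated correlation). ERK feedback and ETS targets had 5 higher and 13 lower (8 and 14 adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.16 with an estimated correlation), their median of -0.26 becoming 0.17 with library totals.

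The 4OHT effect with PP1 differed from that with MEKi at 1829 genes, 1105 higher and 724 lower (edgeR quasi-likelihood). The higher made up 60.4% of these, against 36.6% of 1863 with library totals after the 14 loci had been left out. Spry4 (log2 7.51 ± 0.18, edgeR adjusted p = 4.6e-19), Egr1 (7 ± 0.35), Slc7a7 (4.59 ± 0.18), Myc (4.16 ± 0.31), Etv4 (4.15 ± 0.20), Dusp6 (3.78 ± 0.18) and Spred1 (2.69 ± 0.12) were higher. Atp6v0a4 (-2.85 ± 0.29), Ndrg1 (-2.15 ± 0.16), Nova2 (-1.44 ± 0.15), Dpysl5 (-1.28 ± 0.12) and Mok (-1.18 ± 0.13) were lower. ERK feedback and ETS targets had 20 higher and 0 lower (21 adjusted over the list alone; camera adjusted p = 1.8e-22, and adjusted p = 0.00036 with an estimated correlation), and ribosome biogenesis genes 18 and 0 (22 adjusted over the list alone; camera adjusted p = 7.3e-10, and adjusted p = 0.32 with an estimated correlation).

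**Figure D3:**
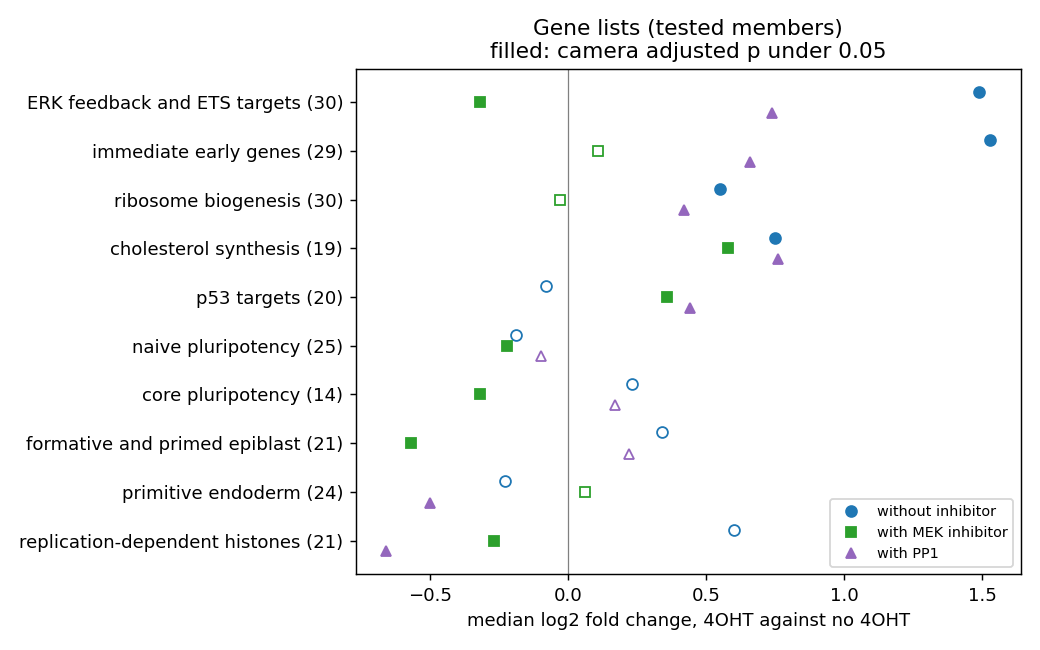
Median log2 fold change of 10 gene lists with 4OHT against its own control, without inhibitor, with MEKi and with PP1; filled points have a camera adjusted p under 0.05 with the preset correlation. Cholesterol synthesis genes lie at 0.75, 0.58 and 0.76 in the 3 conditions, and ERK feedback and ETS targets at 1.49, -0.32 and 0.74.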

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

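The tests of explanations for the lower ERK targets were chosen only after the result was seen, whereas the interaction tests and the tests of other splits of the libraries were planned.

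Differences between the 4OHT effects under different inhibitors are given here because each was tested by an interaction term (edgeR quasi-likelihood). With MEKi the effect differed from that without inhibitor at 6022 genes, and 526 genes were called in opposite directions in the 2 conditions with the difference called. Genes that rose without inhibitor and fell with MEKi numbered 280 (269.4 by chance), and those that fell and rose 246 (299.8 by chance). With TMM scaling, opposite calls were thus about as many as chance gives, or fewer. With library totals as the only scaling, 60 genes rose without inhibitor and fell with MEKi, of 1293 that rose and 193 that fell. Chance counts were not computed for that scaling, so this cannot be said there. ERK feedback and ETS targets were lower as a list (camera adjusted p = 3.3e-14, with 24 of 30 members lower, and adjusted p = 0.0028 with an estimated correlation). On the log2 scale the difference was -7.79 for Spry4, -7.33 for Egr1, -5.59 for Pla2g7, -4.07 for Myc, -3.99 for Etv4, -3.97 for Dusp6, -3.03 for Spred1 and -1.57 for Etv5. It was 2.88 for Arhgap8 and 2.30 for Azin2. With PP1 the effect differed from that without inhibitor at 3943 genes, of which 140 were called in opposite directions in the 2 conditions, and the difference for Esrrb was 0.67. These opposite calls were fewer than chance gives, at 50 (491.8 by chance) for rises without inhibitor and 90 (722.6 by chance) for falls.

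Between PP1 and MEKi, the 4OHT effect differed at 1829 genes, and 316 genes were called in opposite directions with the difference called. Genes that rose with MEKi and fell with PP1 numbered 81 (146.3 by chance), and those that fell with MEKi and rose with PP1 235 (193.2 by chance). ERK feedback and ETS targets were higher with PP1 as a list (camera adjusted p = 1.8e-22, with 20 of 30 members higher, and adjusted p = 0.00036 with an estimated correlation). The log2 difference was 7.51 for Spry4, 7 for Egr1, 4.59 for Slc7a7, 4.16 for Myc, 4.15 for Etv4, 3.78 for Dusp6, 2.69 for Spred1 and 1.32 for Etv5. It was -2.85 for Atp6v0a4, -2.15 for Ndrg1, -1.44 for Nova2 and -1.28 for Dpysl5.

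Of 40 drawn joint splits of the 12 libraries behind the PP1 and MEKi interaction, 4 gave as many called genes as the real one, itself included (1829 genes in the real split, 2390 in the highest other). The 3 others as large all kept the libraries treated with 4OHT in their real split, as 4 of the 39 others did. Such splits keep the difference between the treated groups, so this count decides nothing about chance. The 35 with treated libraries mixed gave at most 0 genes. For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. In each of these, 1 of the 10 splits, the real one, gave as many genes, and the highest other gave 0. The real values were 2188 for MEKi with 4OHT against MEKi, 4661 for PP1 with 4OHT against PP1, 8463 for MEKi with 4OHT against 4OHT, 6238 for PP1 with 4OHT against 4OHT, 4199 for PP1 with 4OHT against MEKi with 4OHT and 11 for PP1 against MEKi.

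ERK target genes were lower with MEKi and 4OHT than with MEKi alone, 13 of the 30 listed members having fallen. Against a single library or the background as the cause, at least 11 of the 13 were still called in each of 7 fits with libraries left out. If uninhibited RNA mixed into the MEKi libraries were the cause, each member would keep a like share of the distance between its levels in DMSO and in MEKi with 4OHT, but the mean shares differed by 116 percentage points (residual SD 25.2), from 14.2 ± 1.37% for Spry4 to 130 ± 88% for Spred3, and by 70 points (residual SD 8.61) without Spred3. A longer time with MEKi in the libraries that also had 4OHT and an effect of 4OHT itself cannot be told apart, since the time with MEKi alone is not given in the sources used here, and that 6 of the 6 members called lower with MEKi against DMSO fell further is expected under both.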

How the results depend on the processing

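The alternatives that left out the 14 high-count loci, the 2 libraries of highest background or the 3 libraries with the largest loci share, or that kept genes of higher average CPM, were chosen after the data were seen, and the others were planned.

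Of the values of named genes under the alternatives, 19578 kept their side of the threshold, 1021 were weaker, 58 stronger and 7 reversed. For list tests these were 1563, 152, 61 and 0. Called values that kept their side also kept their direction. Changes of direction in values called in neither fit were not counted as reversed. Of the counts per comparison, 208 stayed within 1.5 times and 33 moved. Of the overlaps and medians, 33 stayed, 18 moved and 1 reversed.

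Library totals as the only scaling moved most results. Calls numbered 1130 for MEKi with 4OHT against MEKi, 2668 for PP1 with 4OHT against PP1, 20 for MEKi and 14 for PP1 against DMSO, 2153 for PP1 with 4OHT against MEKi with 4OHT, 3 for PP1 against MEKi and 514 for the interaction of PP1 and MEKi. Of genes that rose without inhibitor, 175 rose with MEKi and 646 with PP1, and of those that fell, 64 and 500 fell. Over all genes tested, 9 fell with both inhibitors. Chance counts for these overlaps were not computed under this scaling. The median log2 response of genes that rose was 0.224 with MEKi and 0.514 with PP1. That of genes that fell was -0.117 with PP1 and reversed to 0.139 with MEKi. Genes whose direction reversed were Ppia (0.002) in PP1 with 4OHT against 4OHT, L1td1 (0.015), Cdk1 (0.079) and Chordc1 (0.006) in the interaction of MEKi with no inhibitor, and Wdr43 (0.174), Polr1a (0.117) and Aurka (0.016) in that of PP1. Under this scaling none of these 7 was called by edgeR. With the 14 loci left out as well, the 7 counts were 2462, 4475, 71, 32, 4525, 10 and 1863, within 1.5 times those with TMM, so the lower counts went with the loci. The median of all genes for 4OHT against DMSO stayed at -0.27 (-0.32 with the loci), so most of that shift did not. Nor did all directions return to those with TMM. For PP1 with 4OHT against MEKi with 4OHT, 31.1% of calls were higher (30.7% with the loci, 53.9% with TMM). For MEKi and for PP1 with 4OHT against 4OHT these were 74.1% (80%, 50%) and 73.2% (79.8%, 51.1%). MEKi with 4OHT against MEKi came nearer, at 63.8% (82.9%, 52.1%). Whether the overlaps and their medians changed with the loci was not tested.

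For the other settings the cause was not tested. DESeq2 called 132 genes for MEKi against DMSO, 85 for PP1 against DMSO and 20 for PP1 against MEKi. With DESeq2's size factors the median with PP1 of genes that rose was 0.245. Clone as a block gave 120 for MEKi against DMSO and moved no other comparison's count by more than 1.5 times. It gave 77 genes that rose without inhibitor and fell with PP1 (50 without the block), and 125 that rose with MEKi and fell with PP1 (81 without). With only the groups compared there were 23, 6 and 3 calls for MEKi against DMSO, PP1 against DMSO and PP1 against MEKi. Without the 2 libraries of highest background (MEKi a and MEKi with 4OHT b) there were 1051 for MEKi with 4OHT against MEKi and 34 for MEKi against DMSO. For PP1 against DMSO there were 23 without the 14 loci and 55 without the 3 libraries of largest loci share (4OHT b, MEKi b and PP1 a), which gave 18 for PP1 against MEKi. Among genes that changed at least 2-fold the medians were 0.392 with PP1 for those that rose, and -0.075 with MEKi and -0.55 with PP1 for those that fell.

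Leaving out 1 library at a time, calls ranged from 1380 to 1980 for MEKi with 4OHT against MEKi, 19 to 52 for MEKi against DMSO, 3 to 32 for PP1 against DMSO and 6 to 13 for PP1 against MEKi. The other 8 comparisons stayed within 1.5 times, such as 6268 to 7554 for 4OHT against DMSO and 3516 to 4558 for PP1 with 4OHT against PP1. Where 1 DMSO library was left, the spread was pooled across groups and that library was assumed to vary like the others. The pseudocount and filter for normalized values were not applicable.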

Other observations

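The tests of explanations in this part were all chosen only after the results were seen.

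Cholesterol synthesis genes were higher with 4OHT in all 3 conditions, with 15, 15 and 18 of 19 members called higher without inhibitor, with MEKi and with PP1, and 12 called in all 3. The list calls were lost with an estimated correlation (camera adjusted p = 0.45, 0.16 and 0.2). ERK activation as the whole cause is argued against by MEKi, under which the lowest of the 3 clone medians was 0.43 (log2, with 0.66 and 0.65 in the others). Scaling is argued against, as far as the 5 scalings tried go, by a lowest list median of 0.43 over these and the 3 conditions. An effect of 4OHT or of the 2 h of treatment by a route other than ERK may contribute, and these cannot be told apart because every library with 4OHT had both.

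The share of counts in the 14 high-count loci ran from 9.38% in 4OHT a to 42% in PP1 a. Treatment group as the whole cause is argued against by 67.5% of the sum of squares of the log2 share lying within groups. Within groups, the log2 share was related to the mean log2 CPM of long-lived abundant mRNAs (17 libraries, Pearson's r 0.92, permutation p = 0.001, adjusted 0.001; Spearman's rho 0.86, permutation p = 0.001; r 0.88 without MEKi b and 4OHT b), which is consistent with carry-over of unlabelled RNA. It was also related to the log2 total counts (Pearson's r -0.88, permutation p = 3e-04, adjusted 6e-04, and r -0.86 without PP1 a and PP1 b). Spearman's rho was -0.85 (permutation p = 0.00068, adjusted 0.001). The total is the denominator of the share, so a negative r is partly built in, which the permutations do not allow for. Nor is the total a measured yield, so this relation cannot decide on low yield of the library. Carry-over and low yield both stay open (100000 two-sided permutations within groups, 2 relations tested), and no biological explanation within groups was tested.

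Med24 (chromosome 11, 98704591 to 98729435) had 25241 counts in MEKi a, 2888 in MEKi c and 242 to 1120 in the other 15 libraries. The 13 mitochondrial symbols had 0 counts in each of the 17 libraries.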
